A study of Homo sapiens with 16 samples.

How the data were processed

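RNA was profiled on 16 Affymetrix arrays from MDA-MB-468, an established human breast cancer cell line of the basal-like, triple-negative type. Per the labels' protocols, cells were infected with viral supernatant in 6 µg/ml polybrene, placed under 1 µg/ml puromycin 48 h after infection, and seeded at equal confluence 24 h before RNA extraction. Labelling started from 200 ng of total RNA. Conditioned medium came from mouse L cells (control medium, L-cont) or from L cells that secrete Wnt3A (Wnt3A medium), and was applied for 8 h, per the labels' protocols. The samples form 10 groups. The scrambled control shRNA (shCont) and the hairpins shTCF3-1 and shTCF3-2 were each profiled untreated (1 array), in L-cont medium (2 arrays) and in Wnt3A medium (2 arrays), and a β-catenin hairpin was profiled untreated (1 array). Groups and replicate numbers were taken from the sample titles.

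The deposited values were log2 probe set signals that the authors had summarised before deposit; per the submitters' processing notes, Affymetrix Expression Console and RMA were used, whose versions and settings are not given in the sources used here. RMA corrects background, quantile normalizes probes across arrays and summarises them per probe set, so it removes differences in the overall signal distribution between arrays and compresses changes near the detection floor. Whether the 16 arrays were processed together is not given in the sources used here. The median of the deposited values lay between 5.60 and 5.82 in every array, and no value was centred per gene. Arrays have no read depth, and their number limits the precision.

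Of 33297 probe sets, 19460 were paired with 1 gene symbol by the platform annotation, 1754 with several and 12083 were unlisted there. Only probe sets with 1 symbol were used for genes. By gene ID, 19429 of the 19460 were found in a RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene with more than 1 probe set (769 genes) was represented by the one with the highest mean over the 16 arrays, which left 18417 genes. No filter was set on dim probe sets.

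Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 1 mean per group in a model of all 16 arrays (6 residual degrees of freedom from the 6 groups of 2 arrays, 4.62 prior degrees of freedom, prior SD 0.127). The contrasts were TCF3 knockdown (mean of both hairpins minus shCont, over both conditioned media, 8 arrays against 4), Wnt3A minus L-cont medium in shCont cells (2 against 2), the same over the 3 shRNAs (6 against 6), the knockdown by Wnt3A interaction, and shTCF3-2 minus shTCF3-1 (4 against 4). L-cont medium was compared with untreated cells in an additive model of shRNA and medium on 9 arrays (6 against 3; 5 residual degrees of freedom, 3.68 prior degrees of freedom, prior SD 0.162), since each untreated group held 1 array. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 18417 genes, and a gene passed at an adjusted p under 0.05. Errors given with ± are standard errors (SE) from limma on the log2 scale. Beta-catenin knockdown and the untreated hairpins have 1 array each and were not tested.

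The groups, tests, alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule named, per tested contrast, up to 10 higher and 10 lower genes with the largest log2 change among those that passed and whose arrays did not overlap in any hairpin and medium the contrast averages over. Where fewer than 10 passed, it named the 10 genes with the smallest p. It also named TCF7L1, TCF3 and CTNNB1, up to 4 members per described list with the largest moderated statistic, and for β-catenin knockdown the 10 higher and 10 lower genes with the largest difference among genes with a mean of at least 6. Members of a list named beyond these were chosen after their values were seen.

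The lists held 363 genes, of which 339 were measured: Wnt feedback targets, other reported Wnt targets, TCF/LEF factors and cofactors, Wnt receptors and ligands, basal and myoepithelial markers, luminal markers, pluripotency factors, epithelial-mesenchymal transition, mitotic genes, DNA replication genes, epidermal differentiation, interferon response, NF-kB and inflammatory genes, hypoxia and glycolysis, sterol synthesis, amino acid and unfolded protein stress, immediate early genes, TGF-beta and BMP targets, fibroblast markers, and immune and endothelial markers. List genes without a probe set of 1 symbol were not analysed here; they include TCF7, TP63, KRT17, KRT6A, NANOG and POU5F1. Each list was tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and p-values were adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. For the untreated arrays, only the median of each list is given.

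The conditioned medium groups share replicate numbers in the titles. The difference between replicates 1 and 2 correlated across genes in all 15 pairs of groups, with r between 0.224 and 0.549 (median 0.392) and above 0.1 in all 15, so the numbers were taken to pair the arrays. A fit with the replicate number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Other alternatives left out dim genes, normalized again, subtracted array medians, used a variance trend, array weights, the mean of a gene's probe sets or all probe sets, left out each array in turn, or fitted only the arrays compared.

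The calculations were tested on simulated values for the 18417 genes, with 50 genes changed at each fold. Of genes changed 1.5-fold, 96% were recovered in the knockdown contrast, 46% for Wnt3A in shCont cells, 96% for Wnt3A over the 3 shRNAs, 6% for the interaction, 88% for the hairpin difference and 72% for control medium. Of genes changed 2-fold, 82% were recovered for the interaction and 96% or more elsewhere. Unchanged genes called by mistake numbered 11, 5, 13, 2, 13 and 10 in that order. A list of 18 genes shifted by -0.3 was called in every contrast, and 0 of 19 unshifted lists were. The simulated genes varied independently of each other, so this cannot show how lists of genes that move together are called. No shared difference between replicate numbers was simulated, so recovery in the real arrays may differ. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.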

Results

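Gene expression was measured in MDA-MB-468 cells, a basal-like breast cancer line, after stable infection with a scrambled shRNA (shCont), with the TCF3 hairpins shTCF3-1 and shTCF3-2, or with a β-catenin hairpin. The series addresses the role of TCF3 in the growth of breast cancer cells, and its design asks which genes depend on TCF3, which respond to Wnt3A conditioned medium, and whether that response changes when TCF3 is knocked down. The conditioned medium groups held 2 arrays each, called biological repeats by the submitters, and the 4 untreated groups held 1 array each. The labels do not say whether the repeats came from separate infections, so the p-values measure only the spread between these samples. Arrays of one group correlated at 0.9932 or more across genes, and any 2 arrays in conditioned medium at 0.9779 or more. The untreated shTCF3-2 array stood apart, with a median correlation of 0.9613 to the other 15 arrays.

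The name TCF3 is used for TCF7L1, a factor that binds Wnt-responsive elements and often represses them, and for the gene TCF3, which encodes the helix-loop-helix factors E12 and E47. The labels do not say which was targeted, so both were measured. TCF7L1 fell with each hairpin. In conditioned medium it was 9.69 ± 0.17 (log2, SD, n = 4) with shCont, 7.64 ± 0.26 (SD, n = 4) with shTCF3-1 and 8.32 ± 0.12 (SD, n = 4) with shTCF3-2. The knockdown changed TCF7L1 by -1.71 ± 0.10, leaving 30.6% of the control signal (limma adjusted p = 8.36e-06), with 24.2% left by shTCF3-1 and 38.8% by shTCF3-2. TCF7L1 was higher with shTCF3-2 than with shTCF3-1 by 0.68 ± 0.12 (adjusted p = 0.0162). In untreated cells, TCF7L1 was 10.21 with shCont, 7.60 with shTCF3-1, 8.87 with shTCF3-2 and 9.36 with the β-catenin hairpin.

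TCF3 itself differed by -0.24 ± 0.11 on knockdown, which did not pass (adjusted p = 0.152). It passed with the replicate number as a block (adjusted p = 0.00749), and its adjusted p ranged from 0.00749 to 0.687 over the alternatives. In the untreated shTCF3-2 array TCF3 lay 0.73 above shCont. CTNNB1, which encodes β-catenin, differed by -0.06 ± 0.06 between the TCF3 hairpins and shCont (adjusted p = 0.57). Its untreated value was 12.01 with shCont and 10.84 with the β-catenin hairpin, which left 44.2% of the signal. The untreated shTCF3-1 and shTCF3-2 arrays read 11.73 and 11.42.

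**Figure D1:**
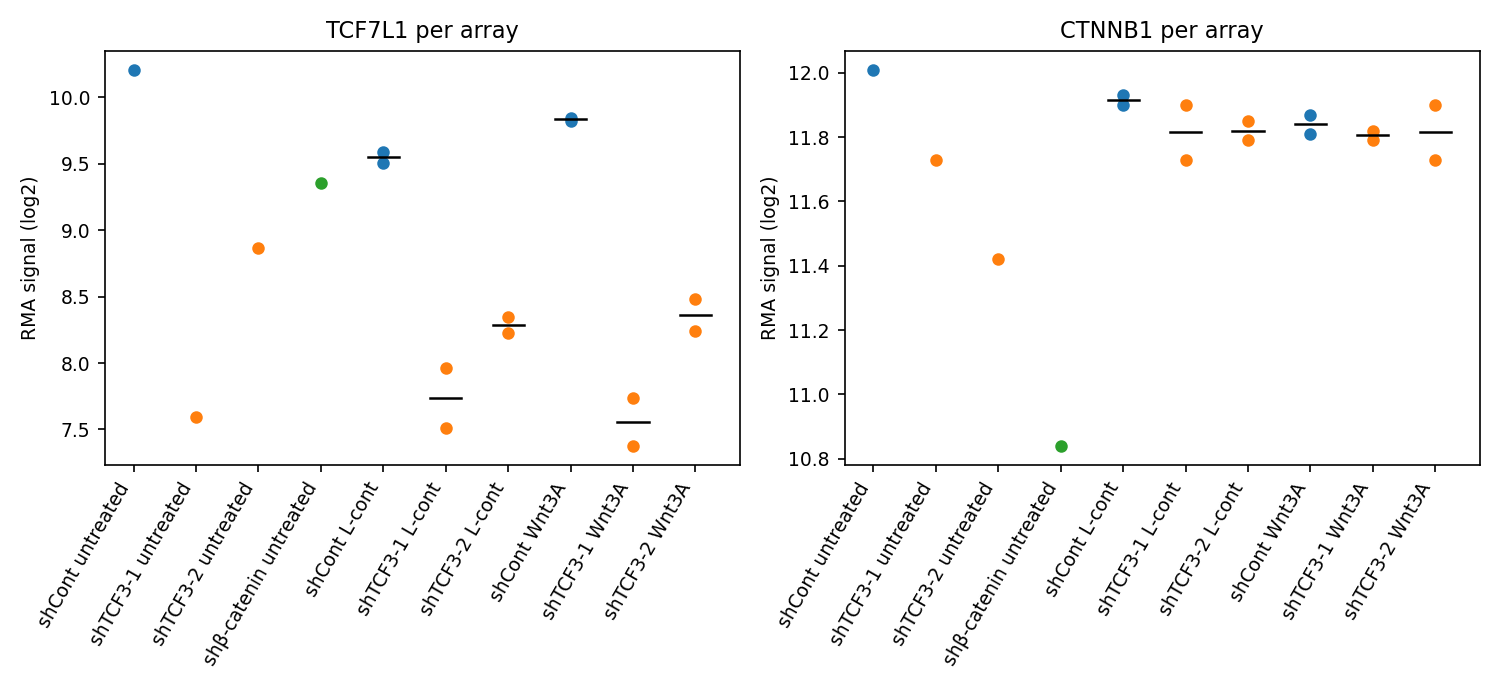
Log2 RMA signal of TCF7L1 (left) and CTNNB1 (right) in each of the 16 arrays by group; points are arrays, bars are means of groups with 2 arrays, and neither axis starts at 0. TCF7L1 lies between 9.51 and 10.21 with shCont and between 7.38 and 8.87 with the TCF3 hairpins, and CTNNB1 reads 10.84 with the β-catenin hairpin.

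The genes named first for TCF3 knockdown in conditioned medium were those with large changes and arrays that did not overlap. ANKRD1, an ankyrin repeat protein induced by YAP, rose 8.01-fold, with an SE of 0.27 on the log2 scale (8 knockdown arrays against 4 shCont arrays). On that scale SCEL, a precursor of the cornified envelope, rose by 2.80 ± 0.13, the metalloproteinase ADAMTS1 by 2.78 ± 0.26, the cytokine receptor IL7R by 2.55 ± 0.27, the matricellular protein CCN3 by 2.43 ± 0.31, the renal amino acid transport protein CLTRN by 2.26 ± 0.36 and INHBA, a subunit of activins, by 2.24 ± 0.33. SERPINB3 (2.82 ± 0.52), SERPINB4 (2.35 ± 0.50) and the calcium-binding protein CALB1 (2.45 ± 0.50) also rose. SERPINB3 and SERPINB4 are near-identical copies whose probes may read each other. The ferroxidase CP fell by 3.82 ± 0.26 on the log2 scale, complement C3 by 2.77 ± 0.26, the BMP and Wnt antagonist SOSTDC1 by 1.86 ± 0.22, the phosphate transporter SLC34A2 by 1.95 ± 0.27, the secreted protein CRISP3 by 2.12 ± 0.42, SYT11 by 1.80 ± 0.16 and RCN1, a calcium-binding protein of the endoplasmic reticulum, by 1.75 ± 0.08. The P450 gene CYP4Z1 (-3.12 ± 0.24), its near-identical pseudogene CYP4Z2P (-2.29 ± 0.36) and FMO6P (-2.41 ± 0.24) were lower too. The values of the CYP4Z copies cannot be separated. The adjusted p of these 20 genes lay between 3.58e-06 for SCEL and RCN1 and 0.00653 for SERPINB4, and all 20 passed without any one array. In L-cont medium alone SERPINB3, CALB1, SERPINB4 and CRISP3 did not pass (adjusted p = 0.059, 0.0618, 0.112 and 0.0571, the highest over their alternatives, whose lowest were 1.62e-04, 1.68e-04, 4.69e-04 and 4.38e-05).

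Mitotic genes fell together. Of 18 measured, 17 fell and 0 rose (18 lower adjusted over the list alone), with a median of -0.577. The fall was larger with shTCF3-1 (median -0.916, 18 lower) than with shTCF3-2 (median -0.242, 2 lower). The cyclin-dependent kinase CDK1 fell by 1.24 ± 0.10, topoisomerase TOP2A by 0.95 ± 0.08, the checkpoint kinase BUB1 by 0.78 ± 0.11 and the spindle protein NUSAP1 by 0.74 ± 0.10. Camera called the list lower (adjusted p = 6.03e-12, and adjusted p = 0.371 with an estimated correlation). DNA replication genes did not shift as a list (adjusted p = 0.932). Of 20 measured, 1 rose, 2 fell and 17 did not pass, with the same counts adjusted over the list alone. CCNE1 rose by 0.61 ± 0.10 while the ribonucleotide reductase subunit RRM2 fell by 0.56 ± 0.10. The replicate block gave 3 and 6.

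Basal and myoepithelial markers rose. Of 11 measured, 7 rose, 0 fell and 4 did not pass (8 higher adjusted over the list alone), and all 11 members are expressed above the median of all values. The actin-binding protein TAGLN rose by 1.21 ± 0.10, the myosin kinase MYLK by 0.96 ± 0.09, the laminin chain LAMB3 by 0.74 ± 0.10 and the integrin ITGB4 by 0.69 ± 0.10. Camera gave adjusted p = 9.66e-07 for the list, and adjusted p = 0.229 with an estimated correlation. Of 18 luminal markers, 6 fell and 1 rose (9 and 3 adjusted over the list alone), with a median of -0.154. AGR2, a secretory disulfide isomerase, fell by 1.68 ± 0.10, the epithelial factor ELF3 by 0.82 ± 0.09 and PROM1 by 0.56 ± 0.07, while MUC1 rose by 0.33 ± 0.10. The luminal list passed camera narrowly (adjusted p = 0.0472), and did not with the replicate block (adjusted p = 0.0838) or with an estimated correlation (adjusted p = 0.345). With the block 9 luminal markers fell and 2 rose. Over the camera alternatives the adjusted p ranged from 0.0397 to 0.345. Fry, which does not compare a list with other genes, gave adjusted p = 0.000692.

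Epidermal differentiation genes moved in opposite directions. Of 22 measured, 11 fell and 5 rose (12 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0681). The keratin KRT10 fell by 1.48 ± 0.09, the protease inhibitor PI3 by 1.31 ± 0.14 and the kallikrein KLK7 by 0.84 ± 0.09, whereas the cornified envelope protein SPRR3 rose by 2.02 ± 0.18. Among 17 genes of epithelial-mesenchymal transition, 6 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.221). The intermediate filament VIM rose by 1.93 ± 0.16, fibronectin FN1 by 1.09 ± 0.16, the repressor ZEB1 by 0.59 ± 0.09 and the gelatinase MMP2 by 0.56 ± 0.10, while CDH1 (E-cadherin) fell by 0.35 ± 0.08.

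Wnt feedback targets did not move one way (camera adjusted p = 0.932). Of 19 measured, 1 rose and 3 fell, with the same counts adjusted over the list alone. The secreted antagonist DKK1 rose 2.83-fold (SE 0.11 on the log2 scale), while its co-receptor KREMEN1 fell by 1.04 ± 0.15, the scaffold AXIN2 by 0.62 ± 0.10 and LGR6 by 0.51 ± 0.15. Among 19 other reported Wnt targets 5 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.216). The ligand BMP4 rose by 0.84 ± 0.10 and PPARD by 0.56 ± 0.08, and the matrix protease MMP7 fell by 0.86 ± 0.13. Among 15 TCF/LEF factors and cofactors 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.989), among them TCF7L1 and the corepressors CTBP2 (-0.59 ± 0.07), TLE3 (-0.32 ± 0.06) and TLE4 (0.47 ± 0.10). Of 30 Wnt receptors and ligands 5 rose and 7 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.989), including RYK (-0.44 ± 0.06), DVL3 (0.39 ± 0.06), WLS (0.43 ± 0.07) and FZD3 (-0.63 ± 0.11). Of 13 pluripotency factors, LIN28B rose by 0.28 ± 0.07, KLF5 fell by 0.20 ± 0.06 and 11 did not pass, also when adjusted over the list alone (camera adjusted p = 0.989). Under the replicate block 2 feedback targets rose and 4 fell, and 1 pluripotency factor rose and 2 fell.

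Camera called none of the other lists. Of 19 TGF-beta and BMP targets 7 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.342). PMEPA1 rose by 0.97 ± 0.09, while the helix-loop-helix inhibitors ID1 (-1.05 ± 0.11) and ID3 (-0.86 ± 0.10) fell. Of 18 NF-kB and inflammatory genes 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.214), among them the cytokines LIF (1.42 ± 0.31), CXCL1 (0.92 ± 0.22) and IL6 (0.88 ± 0.14). Of 19 immediate early genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.147), among them the feedback inhibitors of ERK signalling DUSP6 (1.33 ± 0.14) and SPRY2 (1.26 ± 0.12). Of 21 interferon genes 4 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.989), including HERC5 (0.72 ± 0.12) and IFI6 (-0.68 ± 0.11). Of 17 hypoxia and glycolysis genes 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.932), including ADM (1.06 ± 0.15) and BNIP3 (-0.73 ± 0.10). Of 17 stress genes 5 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.989), including DNAJB9 (0.77 ± 0.12) and PHGDH (-0.64 ± 0.09). Of 15 sterol synthesis genes HMGCS1 (-0.64 ± 0.12) and DHCR7 (-0.43 ± 0.11) fell, also when adjusted over the list alone (camera adjusted p = 0.247). With the replicate block 5 NF-kB genes rose and 2 fell, and 5 immediate early genes rose and 1 fell. The direction of camera, the median or the mean differed in sign for the TCF/LEF factors (median 0.0839, mean -0.0875), Wnt receptors (0.00959, -0.0407), hypoxia (-0.00898, 0.0278) and stress lists (-0.0559, -0.0164, camera direction up).

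Markers of cell types that a pure line should lack were not called as lists, though some members passed. Of 12 fibroblast markers, LUM rose by 0.23 ± 0.06, FBLN1 fell by 0.31 ± 0.06 and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.776). The block gave 2 higher and 1 lower. Only 2 of the 12 are expressed above the median of all values. Of 12 immune and endothelial markers, 4 of them above that median, CSF1R rose by 1.03 ± 0.13, KDR rose by 0.70 ± 0.12, CD14 fell by 1.14 ± 0.21 and PECAM1 fell by 0.31 ± 0.09, with the same counts adjusted over the list alone (camera adjusted p = 0.932).

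Across all genes, 3792 of 18417 passed for TCF3 knockdown in limma, 1938 higher and 1854 lower. After subtraction of array medians the split was 1960 higher and 1276 lower. At least a 1.5-fold change was seen in 1010 of them, and at least a 2-fold change in 245 (159 higher, 86 lower). In 3062 of the 18417 genes the knockdown and shCont arrays did not overlap for either hairpin in either medium, a separation that chance gives in 0.889% of genes, and 2733 of them passed. With the hairpins and media taken alone the count was 4118 for shTCF3-1, 1705 for shTCF3-2, 1550 in L-cont medium and 2079 in Wnt3A medium.

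The hairpins moved many of the same genes. Counting genes that passed with each hairpin alone, 880 were higher with each and 662 lower with each, where independent lists would share 110 and 80.9, and 1 gene moved in opposite directions. Across genes, the changes of the hairpins correlated at 0.879. Both share the shCont arrays, and unchanged groups simulated against shared controls gave 0.503. The covariance was 0.0791 against 0.00581 simulated. With the shCont arrays split so that none was shared, the correlation was 0.699 to 0.709. Genes are not independent replicates, and part of the overlap of calls may come from the shared controls.

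**Figure D2:**
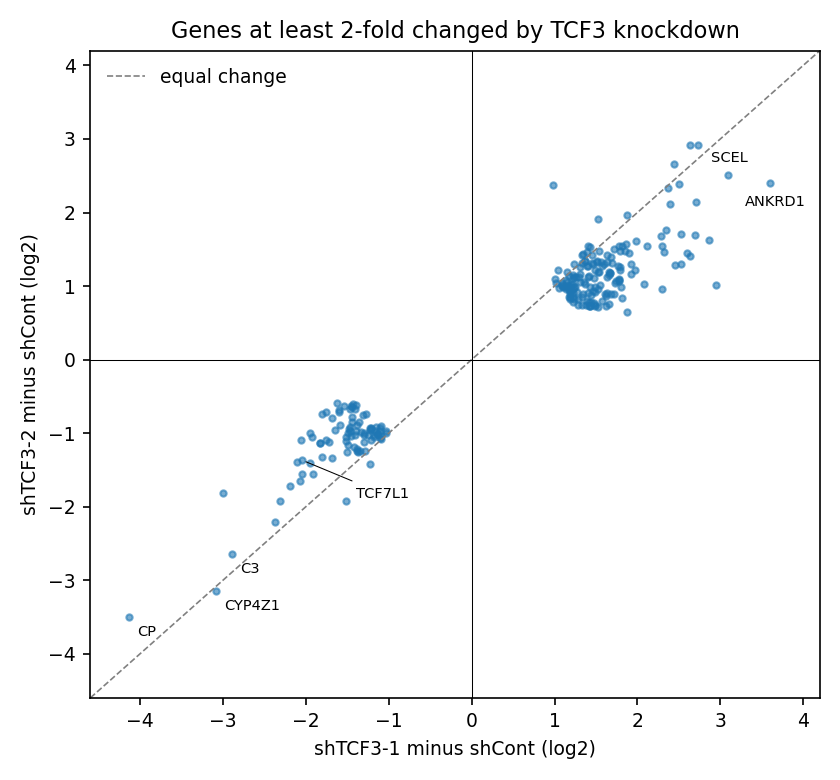
Log2 change to shCont with shTCF3-1 (x axis) and with shTCF3-2 (y axis) for the 245 genes that passed and changed at least 2-fold on knockdown; each point is 1 gene, the dashed line marks equal change, and both axes use the same 4 shCont arrays. All 245 points lie in the quadrants of equal sign, which the choice of genes by their mean change largely fixes; over all genes, with no array shared, r was 0.699 to 0.709.

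The untreated hairpin arrays, 1 each, were set beside these results without a test. Of the 3792 knockdown genes, 95.8% had the same sign in the untreated shTCF3-1 array and 73.4% in the untreated shTCF3-2 array. Of the 245 genes changed at least 2-fold, 245 and 233 had the same sign. Mitotic genes had medians of -1.42 with shTCF3-1 and -0.963 with shTCF3-2 relative to the untreated shCont array. DNA replication genes, not called in conditioned medium, had medians of -0.752 with shTCF3-1 and -0.268 with shTCF3-2. Basal and myoepithelial markers had medians of 0.757 and 0.916. Luminal markers had medians of -0.166 with shTCF3-1 and 0.0649 with shTCF3-2, against -0.154 for the knockdown in conditioned medium. Wnt receptors and ligands had a median of 0.0876 with shTCF3-1 and 0.567 with shTCF3-2, against 0.00959 for the knockdown in conditioned medium.

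Wnt3A medium raised few single genes in shCont cells at this number of arrays. IGFL4, a growth factor-like secreted protein, rose by 2.05 ± 0.18 (2 arrays against 2, limma adjusted p = 0.00528), the Wnt antagonist DKK1 by 1.86 ± 0.19 (adjusted p = 0.00946) and the P450 gene CYP1A1 by 2.33 ± 0.28 (adjusted p = 0.0354). The amino acid transporter SLC7A2 (1.68 ± 0.23), the dynamin DNM3 (1.13 ± 0.15), the Wnt target APCDD1 (1.43 ± 0.23), BMP4 (1.00 ± 0.17), the kinase FRK (-0.80 ± 0.12), FGFBP1 (-0.93 ± 0.14) and LPIN1 (-0.80 ± 0.12) completed the 10 smallest p-values. None of these 7 passed (adjusted p = 0.0662 to 0.165).

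As lists, Wnt feedback targets were higher in shCont cells, with 1 of 19 past the threshold (8 adjusted over the list alone), a median of 0.146 and a camera adjusted p of 1.04e-08. The other reported Wnt targets (median 0.14, adjusted p = 6.76e-05) and the stress genes (median 0.253, adjusted p = 3.39e-08) were higher, and the sterol synthesis genes (median -0.342, adjusted p = 2.28e-13) and interferon genes (median -0.0892, adjusted p = 2.41e-04) lower. None of these 5 calls held with an estimated correlation, at adjusted p = 0.112, adjusted p = 0.0646, adjusted p = 0.135, adjusted p = 0.112 and adjusted p = 0.135 in that order. Adjusted over the list alone, 5 sterol genes were lower, 3 stress genes and 2 other Wnt targets higher, and 0 interferon genes passed in limma, where 789 of all genes had an unadjusted p under 0.05.

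Of all genes, 3 passed for Wnt3A in shCont cells, and with all probe sets tested 0 passed. The 789 genes at an unadjusted p under 0.05 in limma are a share below the 0.05 that unchanged genes would give. That fit counts the shared difference between replicate numbers as spread. With the replicate number as a block 19 passed (14 higher, 5 lower), SLC7A2, DNM3, APCDD1, FRK, FGFBP1 and LPIN1 among them. In that fit 4 feedback targets and 1 stress gene were higher, and the mitotic list was called lower (median -0.0863, adjusted p = 0.0259 with and 0.0739 without the block, and adjusted p = 0.688 with an estimated correlation in the unblocked fit). Without shCont L-cont replicate 2 the count was 0, and without shCont Wnt3A replicate 2 it was 1, so that none of IGFL4, DKK1 and CYP1A1 passed without any one array. In the hairpin cells alone, limma called 0 genes with shTCF3-1, where 1306 had an unadjusted p under 0.05, and 2 with shTCF3-2.

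Averaged over the 3 shRNAs, Wnt3A medium raised 7 of 19 feedback targets of the Wnt pathway, and 12 did not pass. DKK1 rose by 1.04 ± 0.11 (6 arrays against 6), APCDD1 by 1.05 ± 0.13, the scaffold AXIN2 by 0.89 ± 0.10 and the ubiquitin ligase ZNRF3 by 0.80 ± 0.09, and NKD1 (0.93 ± 0.14), RNF43 (0.43 ± 0.07) and LGR6 (0.78 ± 0.14) rose as well. These 7 were higher and 0 of the list were lower (9 and 0 adjusted over the list alone), with a median of 0.186 (camera adjusted p = 8.41e-09, and adjusted p = 0.112 with an estimated correlation). Of 19 other reported Wnt targets, BMP4 (1.26 ± 0.10) and VEGFA (0.32 ± 0.06) rose (8 adjusted over the list alone), with a median of 0.177. This list passed camera with the preset correlation (adjusted p = 8.22e-08) and with an estimated correlation (adjusted p = 0.0172). The ligand WNT5A rose by 1.00 ± 0.12, the only member called over all genes among 30 Wnt receptors and ligands.

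Beyond these lists, among genes whose arrays did not overlap in any shRNA, the largest increases were those of the glucose transporter SLC2A3 (1.94 ± 0.20), KRTAP3-1 (1.87 ± 0.31), the vitamin D hydroxylase CYP24A1 (1.71 ± 0.25), IGFL4 (1.63 ± 0.10), ANKRD1 (1.60 ± 0.25), STC2 (1.37 ± 0.20), the glutathione-degrading enzyme CHAC1 (1.31 ± 0.17), CYP1A1 (1.29 ± 0.16) and the stress-induced cytokine GDF15 (1.16 ± 0.20). The largest decreases among such genes were those of the death ligand TNFSF10 (-0.85 ± 0.17), MUC15 (-0.83 ± 0.13), ARRDC3 (-0.83 ± 0.14), PLEKHS1 (-0.81 ± 0.15), HMGCS1 (-0.80 ± 0.11), EDN2 (-0.79 ± 0.15), PIK3IP1 (-0.71 ± 0.11), TRANK1 (-0.70 ± 0.10), FGFBP1 (-0.69 ± 0.08) and IL17RE (-0.68 ± 0.11). Their adjusted p lay between 2.20e-04 for IGFL4 and 0.0479 for TNFSF10. Of the 20 genes with the largest changes, 6 passed without any one array, namely SLC2A3, IGFL4, CHAC1, CYP1A1, BMP4 and FGFBP1. The increases are relative to L-cont medium, which itself differed from untreated cells. ANKRD1 (-2.02), STC2 (-1.58), CHAC1 (-1.45) and GDF15 (-1.10) were lower in L-cont medium than in untreated cells, and CYP1A1 was already higher (2.62). For these genes the rise over L-cont medium is thus not a rise of that size over untreated cells.

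Genes of amino acid and unfolded protein stress were higher in Wnt3A medium over the 3 shRNAs. CHAC1 and the cystine transporter SLC7A11 (1.15 ± 0.20) rose, 2 of 17 measured (9 adjusted over the list alone), with a median of 0.251 (camera adjusted p = 9.40e-09, and adjusted p = 0.127 with an estimated correlation). Sterol synthesis genes were lower, with HMGCS1, INSIG1 (-0.81 ± 0.13) and SQLE (-0.47 ± 0.09) past the threshold among 15 (7 adjusted over the list alone) and a median of -0.212 (adjusted p = 7.32e-09, and adjusted p = 0.149 with an estimated correlation). The interferon-induced genes IFIT2 (-0.49 ± 0.08), IFIT1 (-0.58 ± 0.10) and OAS1 (-0.37 ± 0.07) fell, 3 of 21 (6 adjusted over the list alone; list adjusted p = 6.48e-06, and adjusted p = 0.112 with an estimated correlation). The immediate early list was higher (median 0.19, adjusted p = 2.45e-04, and adjusted p = 0.233 with an estimated correlation), with KLF4 (0.47 ± 0.08) and SPRY2 (0.66 ± 0.11) past the threshold (7 higher and 1 lower adjusted over the list alone). By shRNA its median was 0.123 with shCont, 0.334 with shTCF3-1 and 0.0946 with shTCF3-2. Camera at the preset correlation called it with shTCF3-1 alone. Limma called 0 members of the mitotic list (1 lower adjusted over the list alone; median -0.197, list adjusted p = 9.70e-06, and adjusted p = 0.432 with an estimated correlation) and 0 of the NF-kB list (4 higher adjusted over the list alone; median 0.0879, list adjusted p = 0.00404, and adjusted p = 0.233 with an estimated correlation), against 2204 of all genes at an unadjusted p under 0.05. The mitotic median was -0.0863 with shCont, -0.432 with shTCF3-1 and -0.061 with shTCF3-2. Without the replicate block, camera at the preset correlation called the mitotic list with shTCF3-1 alone. With the replicate block 7 other Wnt targets, 6 stress genes, 6 NF-kB genes and 7 immediate early genes were higher, and 5 sterol genes, 6 interferon genes, 1 mitotic gene and 1 immediate early gene lower. The other 12 lists were not called by camera, the TGF-beta and BMP targets with the smallest adjusted p (0.0827), of which SMAD7 (0.37 ± 0.07) rose and BMF (-0.77 ± 0.12) fell (4 and 2 with the block, 6 and 3 adjusted over the list alone).

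In all, 194 genes passed for Wnt3A over the 3 shRNAs, 115 higher and 79 lower. In 770 of the 18417 genes the arrays of the media did not overlap in any shRNA, a separation that chance gives in 0.926% of genes, and 170 of them passed. With the replicate block 667 passed (364 higher, 303 lower), with all probe sets 39, in an additive model on 12 arrays 329, and after subtraction of array medians the split was 137 higher and 45 lower. The count fell to 33 and 45 without shCont L-cont replicate 1 or 2, to 41 and 59 without shTCF3-1 L-cont replicate 1 or 2, to 49 without shTCF3-2 L-cont replicate 2, to 58 without shCont Wnt3A replicate 2, to 77 without shTCF3-1 Wnt3A replicate 1 and to 52 without shTCF3-2 Wnt3A replicate 2.

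**Figure D3:**
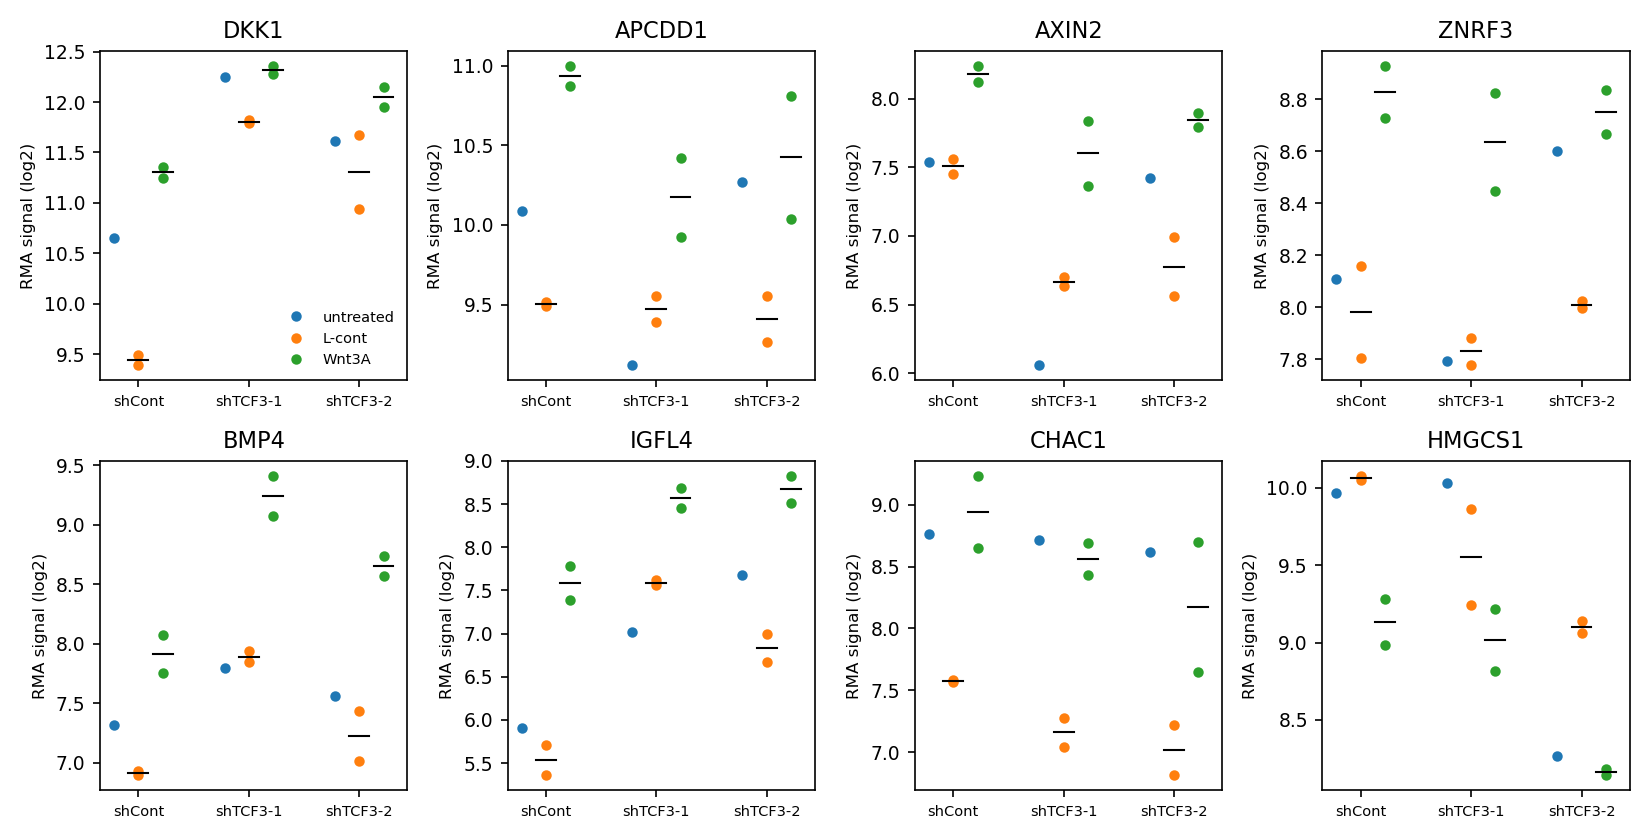
Log2 RMA signal of 8 genes in untreated cells, L-cont medium and Wnt3A medium for each shRNA; points are arrays, bars are means of 2 arrays, and axes do not start at 0. DKK1, APCDD1, AXIN2, ZNRF3, BMP4, IGFL4 and CHAC1 are higher in Wnt3A than in L-cont medium and HMGCS1 is lower, while untreated DKK1 and CHAC1 lie above L-cont medium with shCont.

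Whether the response to Wnt3A differed after TCF3 knockdown was tested as an interaction. For DKK1 the levels in L-cont medium already differed. There it read 9.388 and 9.488 with shCont, 11.82 and 11.79 with shTCF3-1, and 11.67 and 10.94 with shTCF3-2. In Wnt3A medium it read 11.25 and 11.36 with shCont and 11.95 to 12.36 with the TCF3 hairpins, so its smaller change with them did not leave a lower level. DKK1 was raised by 1.86 ± 0.19 in shCont cells and differed by 0.52 ± 0.19 with shTCF3-1 and 0.74 ± 0.19 with shTCF3-2, an interaction of -1.23 ± 0.23 that did not pass over all genes (adjusted p = 1) and passed adjusted over the list alone (adjusted p = 0.00482). SLC7A2 (-1.62 ± 0.28), CYP1A1 (-1.56 ± 0.34), RNF182 (1.33 ± 0.29), ZNF114 (0.65 ± 0.14), SLC41A2 (0.53 ± 0.13), SMAD7 (0.57 ± 0.14), ADGRE4P (-0.52 ± 0.12), SNORA38B (-0.63 ± 0.16) and KAT2B (0.43 ± 0.11) were the others among the 10 smallest p-values, of which SLC7A2 had the smallest, and each had an adjusted p of 1. SMAD7 passed adjusted over the list alone (adjusted p = 0.037). Limma called 0 of 18417 genes, and 0 for either hairpin alone. Of all genes 297 had an unadjusted p under 0.05, a share below the 0.05 that unchanged genes would give. The fit counts the shared difference between replicate numbers as spread. With the replicate block 0 passed as well. Without shTCF3-2 L-cont replicate 2, DKK1 passed (-1.41, adjusted p = 0.0258, in a range of 0.0258 to 1 over the alternatives), the 1 gene called in that fit.

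Of the lists, sterol synthesis (median 0.184, 14 of 15 members above 0, camera adjusted p = 0.00132) and immediate early genes (median 0.0913, 13 of 19 above 0, adjusted p = 0.0143) had a higher interaction. Neither held with an estimated correlation (adjusted p = 0.657 and adjusted p = 0.657) and 0 of their members passed, also when adjusted over the list alone. For immediate early genes the median change in Wnt3A medium was 0.123 with shCont, 0.334 with shTCF3-1 and 0.0946 with shTCF3-2, so only shTCF3-1 lay above shCont. With the replicate block the mitotic list (median -0.138) and the NF-kB list (median 0.12) also passed, at adjusted p = 0.0259 and 0.0267 against 0.0711 and 0.0711 without it, and at adjusted p = 0.937 and adjusted p = 0.657 with an estimated correlation in the unblocked fit.

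The hairpins differed most in mitotic genes, which were lower with shTCF3-1. TOP2A was higher with shTCF3-2 than with shTCF3-1 by 0.75 ± 0.09 (4 arrays against 4), the kinesin KIF11 by 0.72 ± 0.09, BUB1 by 0.93 ± 0.13 and the kinetochore protein CENPF by 0.87 ± 0.12. Of 18 mitotic genes 14 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 0.714 (camera adjusted p = 2.74e-27, and adjusted p = 0.177 with an estimated correlation). Against shCont, the list's median was -0.916 with shTCF3-1 (18 of 18 lower, adjusted p = 1.12e-15, and adjusted p = 0.24 with an estimated correlation) and -0.242 with shTCF3-2 (2 lower, adjusted p = 1.45e-04, and adjusted p = 0.853 with an estimated correlation). Sterol synthesis genes went the other way, with SQLE (-0.80 ± 0.11), INSIG1 (-1.02 ± 0.16), IDI1 (-0.55 ± 0.09), HMGCS1 (-0.65 ± 0.14) and MVK (-0.69 ± 0.15) lower with shTCF3-2, 5 of 15 (12 adjusted over the list alone), and a median of -0.455 (adjusted p = 2.51e-13, and adjusted p = 0.177 with an estimated correlation). The replicate block gave 12 lower sterol genes.

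Smaller list differences passed camera for luminal markers (median 0.098, adjusted p = 0.0222), epidermal differentiation (0.112, 0.0236), interferon genes (0.137, 0.0177), DNA replication (0.143, 0.0153), stress genes (-0.127, 0.00451) and immediate early genes (-0.162, 0.00382). None held with an estimated correlation, at adjusted p = 0.24, adjusted p = 0.241, adjusted p = 0.422, adjusted p = 0.588, adjusted p = 0.446 and adjusted p = 0.436 in that order. The interferon list also did not pass once dim genes were left out (adjusted p = 0.182, in a range of 0.0337 to 0.422 over the alternatives). In each of these lists 0 to 3 members were higher and 0 to 2 lower, among them the luminal AGR2 (0.54 ± 0.12), KRT10 (0.69 ± 0.10), OAS1 (0.55 ± 0.09), VLDLR (-0.58 ± 0.10) and SPRY2 (-0.72 ± 0.14). Adjusted over the list alone, 2 luminal, 4 epidermal, 4 interferon, 4 replication, 1 stress and 1 immediate early gene were higher, and 0, 1, 0, 0, 5 and 3 were lower. Under the replicate block 5 replication genes and 3 interferon genes were higher, 1 stress gene was higher and 4 lower, and 1 immediate early gene was higher and 3 lower.

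Among single genes whose arrays did not overlap in either medium, these lay furthest above shTCF3-1 with shTCF3-2: the ubiquitin ligases RNF167 (1.42 ± 0.12) and RNF6 (1.33 ± 0.09), the histone gene H2BC14 (2.29-fold), SLC16A14 (1.09 ± 0.22), RMI1 (1.09 ± 0.15), PTGIS (1.09 ± 0.22), HMMR (1.07 ± 0.14), NPY1R (1.07 ± 0.22), CDC25C (1.04 ± 0.14) and KIF2C (1.03 ± 0.13). This does not mean a rise above shCont. In conditioned medium RNF6 read 7.354 to 7.65 with shCont, 7.409 to 7.742 with shTCF3-2 and 6.021 to 6.361 with shTCF3-1. RNF167 read 8.845 to 8.937, 8.666 to 8.853 and 7.009 to 7.651 in that order. CDC25C was below shCont with each hairpin (-1.753 with shTCF3-1, -0.7145 with shTCF3-2). SEMA7A (-1.93 ± 0.29), the interleukin receptor IL6R (-1.33 ± 0.18), SPRR3 (-1.23 ± 0.21), SLC2A3 (-1.23 ± 0.25), CST7 (-1.18 ± 0.19), EVI2B (-1.05 ± 0.20), INSIG1, NCR3LG1 (-0.99 ± 0.17), DUSP6 (-0.98 ± 0.16) and NIPAL1 (-0.94 ± 0.12) lay furthest below shTCF3-1 with shTCF3-2 among genes without overlap. SEMA7A was above shCont with each hairpin (2.949 with shTCF3-1, 1.018 with shTCF3-2), while INSIG1 differed from shCont by 0.233 and -0.7892. In total 471 genes passed, 278 higher and 193 lower with shTCF3-2, and 1310 (715 and 595) with the replicate block. After subtraction of array medians the split was 162 higher and 170 lower. The count fell to 239 and 151 without shTCF3-1 L-cont replicate 1 or 2, to 298 and 120 without shTCF3-2 L-cont replicate 1 or 2, to 234 without shTCF3-1 Wnt3A replicate 1, and to 228 and 139 without shTCF3-2 Wnt3A replicate 1 or 2. It was 186 with only the arrays compared and 185 with all probe sets.

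**Figure D4:**
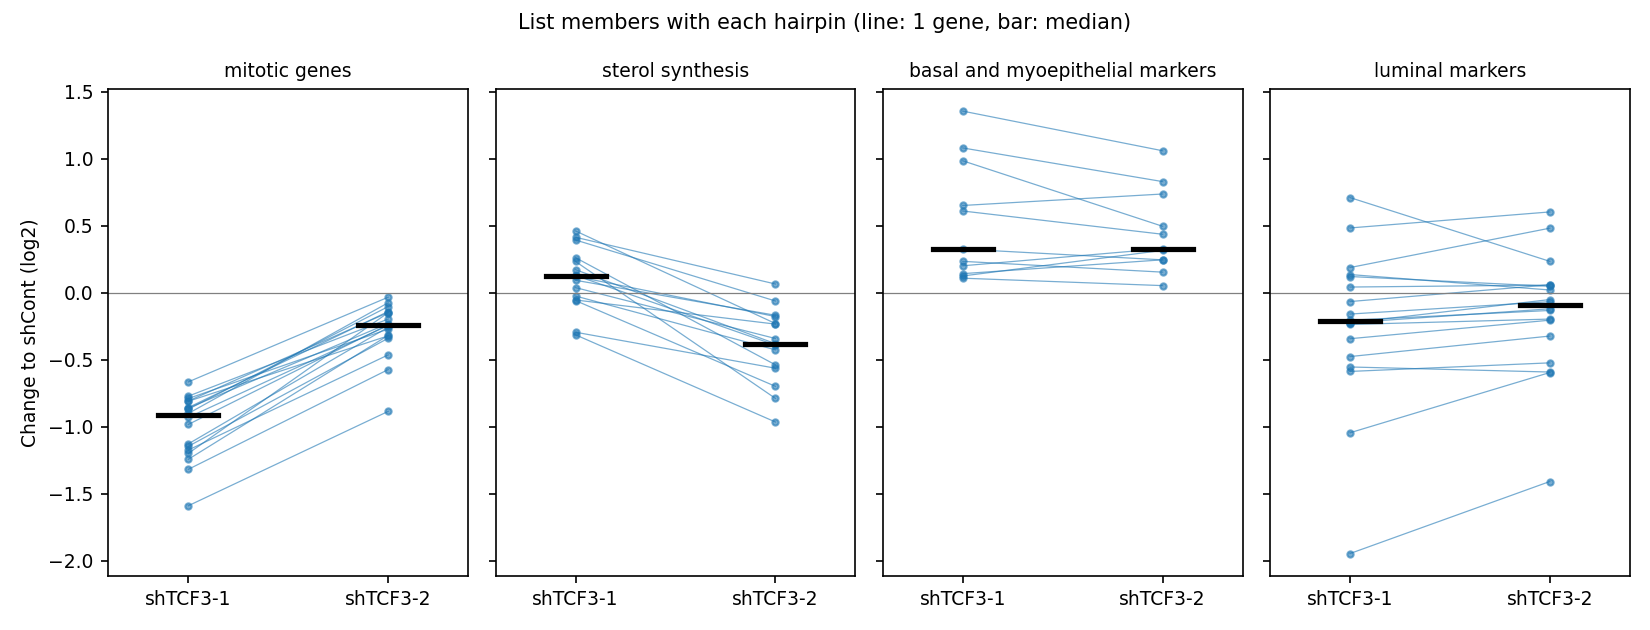
Log2 change to shCont of each member of 4 gene lists with shTCF3-1 and with shTCF3-2; each line joins 1 gene and black bars are medians. Mitotic genes have medians of -0.916 and -0.242 and sterol genes of 0.122 and -0.381, while basal and myoepithelial markers have 0.326 and 0.329.

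L-cont medium was compared with untreated cells as the background of the conditioned medium treatment itself. CYP1A1, a target of the aryl hydrocarbon receptor, rose by 2.62 ± 0.24 in L-cont medium (6 arrays against 3), SLC16A14 by 1.63 ± 0.17, L3MBTL3 by 1.55 ± 0.15, POU2F3 by 1.31 ± 0.17, ANKRD22 by 1.26 ± 0.13, DIXDC1 2.38-fold, CDC25C by 1.22 ± 0.19, THRA by 1.22 ± 0.15, EFNA3 by 1.22 ± 0.20 and GALM by 1.14 ± 0.17. ANKRD1 fell by 2.02 ± 0.25 and CCN2 by 1.93 ± 0.16, both targets of YAP, as did STC2 (-1.58 ± 0.19), CHAC1 (-1.45 ± 0.13), the EGF-family ligand HBEGF (-1.32 ± 0.21), IGFBP5 (-1.23 ± 0.20), GDF15 (-1.10 ± 0.09), SH3TC2 (-1.09 ± 0.16), DUSP6 (-1.04 ± 0.17) and the cornified envelope protein IVL (SE 0.16 on the log2 scale, adjusted p = 0.0384). Of these 20, CCN2 and GDF15 passed without any one array.

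Stress genes were lower in L-cont medium than in untreated cells. Of 17 measured, CHAC1, XBP1 (-0.80 ± 0.10) and DDIT3 (-0.88 ± 0.13) fell (14 lower adjusted over the list alone), with a median of -0.617, and the list passed with the preset (adjusted p = 2.25e-11) and with an estimated correlation (adjusted p = 0.012). Immediate early genes (median -0.362, adjusted p = 3.46e-08, and adjusted p = 0.171 with an estimated correlation; DUSP6 lower, 9 lower adjusted over the list alone) were lower as a list. So were NF-kB and inflammatory genes (median -0.269, adjusted p = 7.46e-05, and adjusted p = 0.131 with an estimated correlation; 8 lower adjusted over the list alone), and TGF-beta and BMP targets (median -0.345, adjusted p = 7.46e-05, and adjusted p = 0.224 with an estimated correlation; CCN2 lower, 4 lower and 1 higher adjusted over the list alone). Other reported Wnt targets had a median of -0.215 (adjusted p = 8.44e-04, and adjusted p = 0.106 with an estimated correlation; 3 lower and 1 higher adjusted over the list alone). Mitotic genes were higher (median 0.524, adjusted p = 1.23e-09, and adjusted p = 0.291 with an estimated correlation), with 0 of 18 called in limma over all genes, where 3718 had an unadjusted p under 0.05, and 14 adjusted over the list alone. DNA replication genes had a median of 0.231 (adjusted p = 0.00618, and adjusted p = 0.552 with an estimated correlation; 1 higher adjusted over the list alone).

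The untreated shTCF3-2 array, which stood apart, entered these list results. Wnt receptors and ligands (median -0.217, adjusted p = 0.0303, and adjusted p = 0.475 with an estimated correlation), epithelial-mesenchymal transition (median -0.162, adjusted p = 0.0354, and adjusted p = 0.421 with an estimated correlation) and epidermal differentiation (median -0.167, adjusted p = 0.0303, and adjusted p = 0.421 with an estimated correlation) were called lower with it and not without it, at adjusted p = 0.441, 0.29 and 0.106, in fits chosen after seeing the data. Over their alternatives the adjusted p ranged from 0.0142 to 0.475, 0.0464 to 0.421 and 0.00445 to 0.421. Of their members IVL alone passed over all genes; 1 Wnt receptor was higher and 1 lower, and 1 epidermal gene higher and 2 lower, adjusted over the list alone. In total 106 genes passed, 79 higher and 27 lower. The group means model on 16 arrays, used for the other contrasts, called 4002 (2451 higher, 1551 lower), while array weights gave 43 and all probe sets 49. The count was 394 without the untreated shCont array, 7 without the untreated shTCF3-1 array, 178 without the untreated shTCF3-2 array, 8 and 12 without shCont L-cont replicate 1 or 2, 9 and 3 without shTCF3-1 L-cont replicate 1 or 2, and 40 and 6 without shTCF3-2 L-cont replicate 1 or 2. HBEGF did not pass without the untreated shTCF3-2 array (adjusted p = 0.0622, in a range of 0.00221 to 0.288).

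Beta-catenin knockdown was profiled on 1 untreated array, set against 1 untreated shCont array without a test or a replicate check. MUCL1, a mucin-like secreted protein, was higher by 2.99, the cobalamin carrier TCN1 by 2.86, CLCA2 by 2.21, CD180 by 1.78, GBP2 by 1.71, PLA2G2A by 1.47, SLCO2A1 by 1.43, A2M by 1.36, SLITRK6 by 1.34 and ANKRD22 by 1.29 on the log2 scale. The chemokine CXCL8 (-2.55), IGFL1 (-2.22), the scavenger receptor OLR1 (-2.16), C3 (-2.05), TNS3 (-1.76), HTR1D (-1.76) and ANKRD1 (-1.70) were lower. So were PSG9 (-2.66), PSG3 (-2.51) and PSG4 (-2.33), members of a family of near-identical genes whose values are uncertain. At least a 2-fold difference was seen in 136 genes, 55 higher and 81 lower.

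Among the lists, NF-kB and inflammatory genes had a median of -0.509 with the β-catenin hairpin, sterol synthesis genes of -0.444 and TGF-beta and BMP targets of -0.324, in 1 array against 1. Other reported Wnt targets had a median of -0.188, epithelial-mesenchymal transition of -0.129 and mitotic genes of -0.187. Wnt feedback targets had a median of -0.0236, within which DKK1 differed by -1.58 and APCDD1 by -0.82. Of the 3792 genes that passed for TCF3 knockdown, 61.3% had the same sign with the β-catenin hairpin, and the changes correlated at 0.112 across all genes.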

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

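The tests of the mitotic slope against the TCF7L1 knockdown and of a response in one shRNA alone, for stress and for sterol genes, and of the spread of those lists between arrays, were chosen after the results were seen. The difference between the hairpins was tested directly, and 471 genes passed. Of the 34 splits of the 8 hairpin arrays that could be fitted (1 could not), 2 called as many as the 375 genes of the real split in a model of hairpin and medium. The highest other count was 406, for the split that followed the replicate number, so chance was not excluded by this count. Among the 8 splits that part as many replicate pairs the real split was the only 1 to reach 375, and the highest other called 0. With the replicate block 1310 genes passed.

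The hairpins also differed in 8 lists, by a median of 0.714 for mitotic genes, -0.455 for sterol synthesis genes, -0.162 for immediate early genes, 0.143 for DNA replication genes, 0.137 for interferon genes, -0.127 for stress genes, 0.112 for epidermal differentiation and 0.098 for luminal markers. None of the 8 held with an estimated correlation (adjusted p = 0.177 to 0.588). The response to Wnt3A differed between knockdown and shCont cells, by the interaction, for sterol synthesis genes (0.184) and immediate early genes (0.0913), at an adjusted p of 0.00132 and 0.0143 with the preset correlation, which neither list kept with an estimated correlation. The Wnt3A medians with shCont, shTCF3-1 and shTCF3-2 were -0.342, -0.095 and -0.217 for sterol genes. They were 0.123, 0.334 and 0.0946 for immediate early genes, where shTCF3-2 did not lie above shCont. Probe sets without a single gene, 13837 in number and used only where all probe sets were tested, held 498 past the threshold on TCF3 knockdown (179 higher, 319 lower). That was 3.6% of them, against 15.8% of single-gene probe sets. The threshold was adjusted over all 33297 probe sets, so it does not fix the share of false calls within this group.

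Mitotic genes were lower with shTCF3-1 than with shTCF3-2. Under another scaling the difference stayed at 0.686 or more. RMA had already quantile normalized the values, and the other scalings moved the hairpin median of all genes by only -0.016 and -0.028. They could hardly have removed the difference, so they do not decide about array scaling. The tables argue against one set of replicates, with 0.689 in replicate 1 and 0.784 in replicate 2. A knockdown effect in proportion to TCF7L1 stays open. In conditioned medium the slope of the shTCF3-2 change on the shTCF3-1 change over the 18 genes was 0.298 (SE 0.0348 across genes). It lay below the TCF7L1 ratio of 0.668 and the slope of 0.662 over all genes called on knockdown. Genes are not independent, so that SE does not measure the spread between arrays. The list means were -1 ± 0.132 with shTCF3-1 and -0.278 ± 0.132 with shTCF3-2 (SE between arrays). The mean with shTCF3-2 lay above 1/2 of that with shTCF3-1 by 0.224 ± 0.114 (SE between arrays), which did not pass. That bound is more lenient than the TCF7L1 ratio of 0.668, so it cannot say whether the means depart from that ratio, and the means were not tested against 0.668 itself. In the untreated arrays, 1 each, the medians were -1.42 and -0.963 and the TCF7L1 changes -2.61 and -1.34, and an effect of one hairpin on other transcripts or a different growth state could also give the pattern and was not tested.

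Stress genes were higher and sterol genes lower in Wnt3A medium as lists with the preset correlation, though not with an estimated correlation (adjusted p = 0.127 and 0.149), and 2 of 17 and 3 of 15 members passed. A content of the conditioned media other than Wnt3A stays open for the stress genes. Wnt3A medium lay nearer to untreated cells (median -0.235) than L-cont medium did (-0.617). Across these genes the change from untreated cells to L-cont medium correlated with the change from L-cont to Wnt3A medium at -0.748 (-0.766 and -0.73 with separate control arrays). An effect of Wnt3A on the same genes would give the same sign, so the correlation cannot separate the causes. For sterol genes that correlation was 0.334 and 0.183, and Wnt3A medium lay below untreated cells (-0.319). A response in one shRNA alone stays open: the second largest stress median was 0.253 and the second lowest sterol median -0.217, but the bounds were set after the smallest medians, 0.0953 and -0.095, had been seen, and the list means over arrays (0.392 ± 0.141 for stress and -0.359 ± 0.143 for sterol genes in the second shRNA) did not pass when corrected for 3 shRNAs. Wnt3A itself remains open, since it was applied only in its own medium and cannot be separated from it here.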

How the results depend on the processing

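The additive model without the untreated shTCF3-2 array and the control medium list tests without that array were chosen after seeing the data. TCF3 knockdown genes numbered 3792, and 1705 with shTCF3-2 alone, 1550 in L-cont medium alone, 2079 in Wnt3A medium alone, 1542 past the threshold with each hairpin alone in the same direction, and 1010 with at least a 1.5-fold change; these settings use fewer arrays or a stricter rule. Without any one array the knockdown count was 2572 to 3794, and additive models with untreated arrays gave 3683, or 4939 without the untreated shTCF3-2 array. Testing all probe sets gave 0 for Wnt3A in shCont cells (3 before), 39 over the 3 shRNAs (194 before), 185 for the hairpin difference (471 before) and 49 for control medium (106 before); more features were tested and the cause was not tested further. The replicate block gave 19, 667 and 1310 for the first 3 of these, and an adjusted p of 0.00749 for TCF3 at the same log2 change of -0.238 (0.00749 to 0.687 over its alternatives). The block ended the luminal call on knockdown, added the mitotic list for Wnt3A in shCont cells and the mitotic and NF-kB lists for the interaction, and added 6 genes for Wnt3A in shCont cells (SLC7A2, DNM3, APCDD1, FRK, FGFBP1 and LPIN1). It raised counts of list members that passed, as given beside those lists, and changed no other call among the total counts, list tests and genes named by the rule in the 5 contrasts within conditioned media, and was not fitted for control medium. For Wnt3A over the 3 shRNAs, 63 genes changed at least 1.5-fold and an additive model on 12 arrays gave 329. With only the arrays compared the hairpin difference gave 186, where fewer arrays set the spread. Control medium gave 43 with array weights and 4002 in the group means model on 16 arrays; the cause was not tested. Without any one array the counts were 0 to 2 for Wnt3A in shCont cells, 33 to 261 over the 3 shRNAs, 0 to 1 for the interaction, 120 to 484 for the hairpin difference and 3 to 394 for control medium. The lowest and highest came without shCont L-cont replicate 2 and without replicate 1 of either shCont medium, without shCont L-cont replicate 1 and shTCF3-1 Wnt3A replicate 2, with 1 only without shTCF3-2 L-cont replicate 2, without shTCF3-2 L-cont replicate 2 and shTCF3-1 Wnt3A replicate 2, and without shTCF3-1 L-cont replicate 2 and the untreated shCont array. An arm left with 1 array was assumed to vary like the other groups. Of results for named genes, 589 stayed on their side of the threshold for knockdown (4 lost, 1 gained), 315 for the hairpin difference (59 lost), 342 for Wnt3A over the 3 shRNAs (98 lost), 224 for control medium (116 lost), 106 in shCont cells (12 lost, 12 gained) and 227 for the interaction (1 gained), and no result reversed. An estimated correlation ended 34 of 36 list calls and fry 21 of 36. Another scaling changed the sign of 0 of the 36 list medians and moved the median of all genes by 0.047 or less. Other probe sets of the targeted transcripts were not run, since each transcript has 1. Dim signals near background limit the size of the changes that RMA values can show.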

Other observations

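The tests of 2-fold hairpin genes for a wrong label and of feedback targets raised by knockdown were chosen after the results were seen. Of the 194 Wnt3A genes 111 also passed on knockdown, 91 in the same direction and 20 in the opposite one. Independent lists would share 39.9. Genes are not independent, both comparisons use the same 12 arrays, and the overlap that chance would give was not simulated. ANKRD1, DKK1 and BMP4 were higher in each comparison, while AXIN2 and LGR6 were higher with Wnt3A and lower on knockdown. The hypothesis that knockdown of a repressor raises the feedback targets that Wnt3A raised was examined over the 7 called in Wnt3A medium. On knockdown 1, DKK1, was called higher and 2, AXIN2 and LGR6, lower. NKD1 (0.26 ± 0.14), RNF43 (-0.17 ± 0.08), ZNRF3 (-0.10 ± 0.09) and APCDD1 (-0.35 ± 0.14) did not pass. These targets were thus not called higher as a set. The bounds were set once these calls were known, so the count describes them and cannot test the hypothesis.

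A further hypothesis was that β-catenin knockdown moves Wnt3A genes the opposite way. Of the 194 Wnt3A genes, 129 (66.5%) had the opposite sign in the untreated β-catenin array, among them DKK1 (-1.58) and APCDD1 (-0.82). This share lay at percentile 100 of 10000 random gene sets matched on mean expression, whose median was 51.5%, and the comparisons share no array. Of 115 genes higher with Wnt3A, 82 were lower with the β-catenin hairpin, and of 79 lower genes 47 were higher. Genes are not independent and there was 1 array of that hairpin, so the percentile measures no spread between arrays, and the array itself may contribute to the share.

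The untreated shTCF3-2 array stood apart, with 2490 genes at least 2-fold from the untreated shCont array (776 higher, 1714 lower), against 972 for shTCF3-1 and 136 for the β-catenin hairpin. Poor RNA or hybridisation may have contributed: over 360 olfactory receptor genes the SD of its difference to shCont was 0.168, against 0.148 and 0.134, a ratio of 1.13, under a bound that was wrong because those genes lie near the floor (median 3.80), where RMA compresses differences. A wrong label stays open, as 74.7% of the 471 hairpin difference genes and 88.9% (16 of 18) of those at least 2-fold apart differed the same way between the untreated hairpin arrays. In the direction of its label, TCF7L1 stood at 39.4% of shCont (38.8% with shTCF3-2 in conditioned media, 16.4% with untreated shTCF3-1), RNF167 at 8.97 (7.36 with untreated shTCF3-1, but 8.89 with untreated shCont), and 233 of the 245 2-fold knockdown genes had the same sign. RNF6 was less clear. It read 6.98, against 6.53 with untreated shTCF3-1, 7.58 with untreated shCont and 7.41 to 7.74 with shTCF3-2 in conditioned media. The knockdown itself also stays open, since 76.1% of the 2490 genes had the sign of the shTCF3-2 change in conditioned media, against 99.1% of the 972 for shTCF3-1.

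Other splits of the same arrays were fitted with the other factor kept in the model. For TCF3 knockdown, 1 of 100 splits drawn from 495, the real one with 3710 genes, called as many, and the highest other called 432. Among the 81 splits that part as many pairs the real one was also the only 1, with 1675 the highest other. No other split drawn thus reached the real count. Most splits mix arrays of different shRNAs, and separate infections are not documented. A difference between the infected lines that is not due to the hairpins was therefore not tested. For Wnt3A over the 3 shRNAs, 2 of 100 splits drawn from 462 called at least the 329 genes of the real split, a share under 0.05. The other was the split by replicate number with 1974 genes, several times the real count, which points to a structure of the samples along that number. Among the 32 splits that part as many pairs the real one was the only 1 and the highest other called 0, and the replicate block gave 667 genes. For control medium, 1 of 81 splits (3 more could not be fitted), the real one with 106 genes, called as many, and the highest other called 0. No other split thus reached the real count. The untreated side held 1 array per shRNA, so a difference between cultures other than the medium was not tested. The count also depended strongly on single arrays, as given above.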
